A study of Mus musculus with 12 samples.

How the data were processed

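RNA from 12 samples of cancerous urogenital tissue of mice was profiled on 12 two-colour Agilent arrays, 4 for each of 3 genotypes. Per the labels' protocols, total RNA was taken with Trizol, 2.5 µg was labelled directly as cDNA, the sample carried the red dye and a universal mouse reference the green dye, both of the Alexa series. No dyes were swapped, so a dye effect stands in every ratio and cancels between genotypes only where it is the same on each array.

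The scanner files hold spot intensity values that are not yet normalized, per the file headers made by Feature Extraction 10.7.3.1 on array design 014868. The files give the median signal and median background of each spot. The plan written before the data were examined named mean signals, which the files lack, so medians were used. The files also hold the Feature Extraction log10 ratio of red over green, deposited with its own background subtraction and dye normalization. The authors' table of processed values holds log2 ratios, as a comparison with the scanner values showed. Its slope against the scanner's log ratio, put on the log2 scale, was 0.973 to 0.992 per array, with r from 0.988 to 0.997. Only spots bright in both channels entered this comparison. The table's medians per array ran from −0.00212 to 0.0326. The table's direction is sample over reference and its scale is log2. How its background was treated stays unknown. The log10 ratios and the authors' log2 table served as alternatives.

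Each array held 45018 spots, of which 1639 were controls. Spots marked in the files as non-uniform or as population outliers were left out, and saturated spots were to be kept, although the files mark none as saturated. Over the arrays 4.42% of spots were left out, and 6737 of the features tested lacked a value on at least 1 array. Background was corrected with the normexp method of limma 3.58.1 (offset 50), and log2 ratios were normalized within each array by loess, with control and left-out spots at weight 0. Spots of 1 probe were averaged.

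The background step departs from the plan, and this was decided after counts of called genes had been seen. On HET 4 the noise that normexp estimated was 323 in the sample channel and 601 in the reference channel, against at most 21.5 and 20.7 on the other 11 arrays. A few spots whose background reading exceeded the spot by over 50 set these estimates. The estimates were therefore made without such spots, which numbered 0 to 7 per array in the sample channel and 0 to 12 in the reference channel, and these spots were also left out as values. Counts with all spots in the estimate, as planned, stand beside the main counts in the report.

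Probes were named through their accession, without version, in the mouse RefSeq gene table of assembly GRCm38, used for names alone. Of 33272 distinct accessions 17317 matched a current symbol. The scanner files' own header names an older build, so no coordinates are given. A probe entered if the sample channel was well above background on at least 3 of 4 arrays of at least 1 genotype. For a gene with several such probes, as 4844 genes had, the probe of highest mean brightness was used. This left 25254 features, 15184 with a gene symbol and 10070 without.

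Genotypes were compared with limma on log2 ratios in a single fit of the 3 group means, in R 4.3.3, with p-values adjusted by Benjamini-Hochberg within each contrast and a threshold of 0.05. The contrasts were KO against WT, HET against WT, KO against HET, and HET against the midpoint of WT and KO, with an F test over the 3 genotypes. Gene lists, 32 in number, were fixed before the data were examined. They cover the microRNA pathway and microRNA targets, prostate epithelial states, tumour pathways, markers of other cell types and housekeeping genes. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over lists within a contrast. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were run beside it, with outlier spots kept and 2 remaining gaps filled with the group mean. A list score is the mean over members of the log2 ratio less the gene's mean. Single values were compared by two-sided exact permutation tests, for which 4 against 4 allow a smallest p of 0.0286.

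The rule for named genes, also fixed before the data were examined, takes for each contrast the 8 largest changes per direction among called genes with a full symbol and no overlap between groups. Where fewer pass it adds genes of lowest p up to 4 per direction, described as not passing. From a list in which no member passes it takes the member of lowest p. Dicer1 and Pten are always given. List members beyond this rule, picked by their adjusted p over the list alone, were chosen after their values were seen.

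Tested on simulated data for KO against WT over 25043 genes, the fit recovered 36 of 67 genes shifted by 1 on the log2 scale (53.7%), 61 of 67 shifted by 2 (91.0%) and 66 of 66 shifted by 3, with 10 false calls. In 5 simulations without any change it called 0 genes. Both shifted lists were called and 0 of 30 others. The simulated genes varied independently of each other, so these runs do not show how often lists of correlated genes are called falsely.

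Alternatives changed the background correction, the offset, the normalization, the probe filter and the choice of probe, the authors' and the scanner's ratios, the sample channel alone, slide or replicate number as a block, array weights, trended and robust moderation, fits of 2 genotypes, and left out the 2 arrays of smaller RNA amount or each array in turn. Fits with the outlier spots kept, with the seminal vesicle score as a covariate, and with array position on the slide in the model were added after the data were seen. An F test exact for missing values was added then too, since limma's F is approximate there. Normexp on all spots was the planned main setting and became an alternative after counts had been seen. Fits with a block or a covariate were computed on each gene's own arrays and moderated by limma, and a contrast that those arrays cannot estimate was left out. With position in the model this left 21276 genes for KO against WT. Tests of seed sites were planned only for the case that 3′ untranslated regions were given, and none were.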

Results

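Gene expression was measured in cancerous urogenital tissue from 12 samples, 4 of each of 3 genotypes. In all of them Pten, a brake on PI3K signalling, was deleted by Cre under a probasin-based promoter, which is active in prostate epithelium. The genotypes differed in floxed Dicer1, the gene of the enzyme that cuts microRNA precursors. WT samples kept intact Dicer1, HET samples carried a heterozygous deletion, and KO samples carried a homozygous deletion. The labels name a comparison of the 3 genotypes, which asks how lower Dicer activity changes expression in these tumours. The labels do not say that each sample came from a separate animal, so each p-value of a single gene or score measures the spread between samples. Camera at the preset correlation compares the genes of a list with the other genes. Its p-values do not measure the spread of a list between samples.

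Values are log2 ratios of a sample to a common mouse reference on the same array. The share of spots well above background in the sample channel ran from 58.0% (HET 3) to 87.4% (KO 3), and in the reference channel from 52.5% (KO 4) to 77.9%. The arrays lay on 3 slides, each with arrays of every genotype, but KO and WT arrays shared no position on the slide. HET arrays shared position 3 with WT 2 and position 2 with KO 1, so that a fit with position in the model rests on these arrays. For KO 3 and KO 4 the labels name 2 and 1 µg of RNA, below the 2.5 µg of the protocol. Across probes, the correlation between arrays averaged 0.704 within a genotype and 0.683 between genotypes.

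The targeted genes gave no check of the labels, because the positions of their probes relative to the deleted exons are unknown. The Dicer1 probe used had a mean log2 ratio of 0.23 ± 0.21 in WT, 0.10 ± 0.24 in HET and 0.12 ± 0.07 in KO (SD, n = 4 each, KO against WT exact permutation p = 0.343). A second Dicer1 probe gave 0.43 ± 0.44, 0.04 ± 0.24 and −0.25 ± 0.12 (SD, n = 4 each, KO against WT exact permutation p = 0.0571, unadjusted limma p = 0.0059). Its means thus fell in the order WT, HET, KO. For Pten, deleted in every genotype, the probe used differed between KO and WT by 0.06 with only 2 WT values (exact permutation p = 0.933). A second Pten probe differed by 0.83 (exact permutation p = 0.0571, unadjusted limma p = 0.00399), and another, which failed the brightness filter, by 0.24 (exact permutation p = 0.4).

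Genes of seminal vesicle secretion differed widely between samples of the same genotype. Svs2 ran from −0.22 to 10.55 on the log2 scale, a 1749-fold range, and Svs4 from −0.10 to 11.08. Svs2 exceeded 4 on 6 arrays, WT 1, WT 2, HET 3, HET 4, KO 2 and KO 3. The mean list score was 0.26 in WT, 0.02 in HET and 0.04 in KO, and the list was called in no contrast (camera adjusted p = 0.848 for KO against WT).

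**Figure D1:**
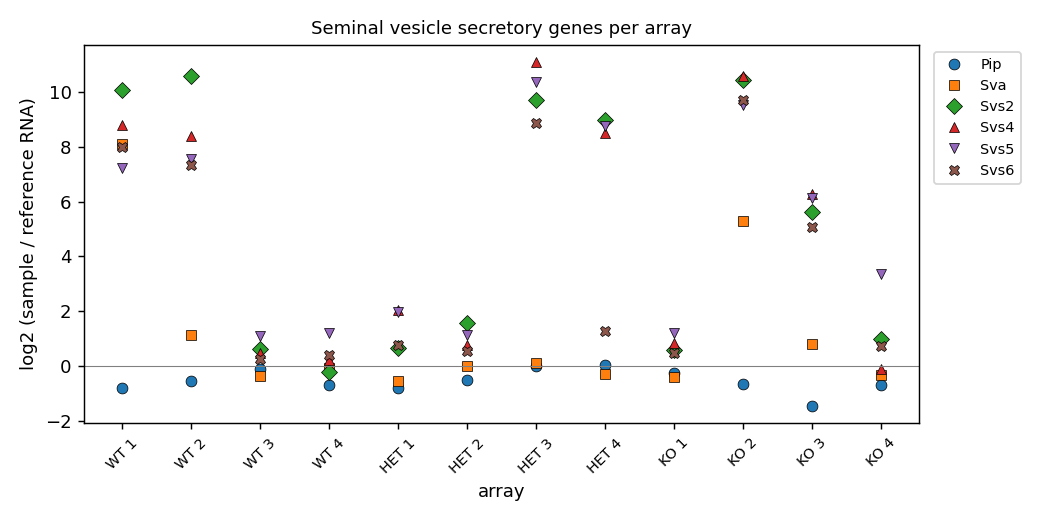
Log2 ratio of sample to reference for 6 seminal vesicle secretory genes on each of the 12 arrays, grouped by genotype. Svs2 spans −0.22 to 10.55, and each genotype holds arrays with high and low values.

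The comparison of KO with WT asks what the loss of both copies of Dicer1 changes in a Pten-null tumour. Immediate early genes, which cells switch on within minutes of a stimulus, stood higher in KO as a group, and interferon response genes stood lower (adjusted p = 0.111 and adjusted p = 0.755 with an estimated correlation). Fos was 3.49-fold and Egr1 3.31-fold higher in KO than in WT, and Lcn2, which encodes the iron-binding acute phase protein lipocalin 2, was 8.25-fold lower. Known targets of the let-7 microRNAs also stood higher, in 17 of 21 measured members (adjusted p = 0.111 with an estimated correlation). No single gene passed the test over all genes in the main setting, with 1 probe per gene. Ltf, Basp1 and Spink5 passed in a fit of all probes, and 4 genes passed with normexp on all spots.

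Limma called 0 of 25043 genes at an adjusted p under 0.05, and the lowest adjusted p was 0.0607. At an unadjusted p under 0.05 there were 2311 genes, 889 higher and 1422 lower in KO, where chance gives 1252. Spink5, a serine protease inhibitor, was higher in KO by 4.04 (SE 0.41, adjusted p = 0.0607 by limma), with values on 2 KO arrays. Basp1 was lower by −2.80 (SE 0.37, adjusted p = 0.0641), a 6.96-fold difference. Emid1, a gene of the extracellular matrix, was higher by 2.52 (SE 0.35, adjusted p = 0.0963), and the chromatin factor Setd5 was higher by 0.91 (SE 0.15, adjusted p = 0.132), although 2 other Setd5 probes gave −0.23 and 0.23. Egr1 was higher by 1.73 (SE 0.30, adjusted p = 0.132). Snx11, Galnt10 and H2-T22 were lower by −1.21, −1.41 and −1.72, with adjusted p of 0.0963, 0.110 and 0.117, Snx11 being above background on 2 of 4 KO arrays and H2-T22 having 2 WT values. With slide as a block the differences were 4.13 for Spink5, −2.85 for Basp1, 2.21 for Emid1, 0.95 for Setd5 and 1.58 for Egr1. Within slides 1, 2 and 3 Basp1 differed by −2.22, −2.92 and −3.74, and Egr1 by 1.27, 1.43 and 2.30.

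Of the immediate early and heat shock list, 13 of 15 measured members were higher in KO, with a median of 0.63 (camera adjusted p = 1.02e-08, adjusted p = 0.111 with an estimated correlation). Adjusted over the list alone, 5 members passed, and 0 did over all genes. These were Fos (1.80, SE 0.33), Egr1, Dusp1 (1.26, SE 0.25), Ier2 (1.19, SE 0.25) and Zfp36 (0.76). The list score differed by 0.65, by 0.61 with slide as a block, and by 0.61, 0.98 and 0.10 within slides 1, 2 and 3. It differed by 0.94 (SE 0.62) with position in the model.

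Interferon response genes were lower in 21 of 22 members, with a median of −0.72 (camera adjusted p = 0.000101, adjusted p = 0.755 with an estimated correlation). Adjusted over the list alone, 0 members passed. The score differed by −0.74, by −0.76 with slide as a block, and by −1.09, 0.29 and −1.79 within the slides, so slide 2 went the other way. WT 3, at 1.41, set much of it, with −0.32 when it was left out and −1.14 without WT 2. Neutrophil and myeloid suppressor markers were lower in 12 of 13 members (median −0.30, camera adjusted p = 0.00131, adjusted p = 0.375 with an estimated correlation). Adjusted over the list alone, 2 of them passed, Ltf, the gene of lactoferrin, at −2.66 (SE 0.52, 2 WT values) and Arg1, the gene of arginase 1, at −1.70, with overlap between the groups and above background on 2 KO and 3 WT arrays (exact permutation p = 0.143). A second, dimmer Ltf probe gave −3.55 (SE 0.31) and passed in a fit of all probes (adjusted p = 0.00113). Hypoxia and glycolysis genes were lower in 11 of 15 members (median −0.59, camera adjusted p = 0.0152, adjusted p = 0.755 with an estimated correlation). The 4 members that passed over the list alone were Pdk1 (−1.35), the glucose transporter Slc2a1 (−1.27), Pgk1 (−0.84) and Aldoa (−0.61), with overlap between the groups for Pdk1 and Aldoa. The hypoxia score differed by −0.39, by −0.19 without WT 3, −0.25 without WT 4 and −0.59 without WT 2, and by 0.58 (SE 0.56) with position in the model.

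Among epithelial lists, proximal luminal progenitor genes were lower in 13 of 16 members (median −0.49, camera adjusted p = 0.0146, adjusted p = 0.755 with an estimated correlation). Their score differed by −0.62, by −0.32 without WT 3 and by −0.37 (SE 0.98) with position in the model. Over that list alone Basp1 passed as lower and Psca, a prostate stem cell antigen, passed as higher (2.48, SE 0.73). The androgen-regulated defensin gene Defb50 was higher by 4.68 (SE 1.04, adjusted p = 0.0147 over its list alone), with overlap between the groups, while its luminal secretory list was not called (camera adjusted p = 0.752).

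The let-7 target list had a median of 0.27 (camera adjusted p = 0.000391, adjusted p = 0.111 with an estimated correlation). Its member of lowest p, Igf2bp2, an RNA-binding protein gene, was higher by 1.08 (SE 0.29, adjusted p = 0.286). The let-7 score differed by 0.25, by 0.21 with slide as a block, and by 0.12, 0.38 and 0.09 within the slides. It differed by 0.67 (SE 0.17) with position in the model. Targets of other microRNAs were called as higher (camera adjusted p = 0.0201, adjusted p = 0.154 with an estimated correlation), although 14 members were higher and 13 lower, and the median was 0.000313 against a mean of 0.142. Their score differed by 0.15, and by 0.48 (SE 0.13) with position in the model. Reck, an inhibitor of matrix metalloproteases, had the lowest p there, at 0.89 (SE 0.27, adjusted p = 0.356). Genes of microRNA biogenesis were higher in 9 of 15 members (median 0.16, camera adjusted p = 0.0152, adjusted p = 0.557 with an estimated correlation). Over that list alone 2 passed, Tnrc6a, a partner of Argonaute proteins, at 1.09 (SE 0.25), with 2 other probes at 0.10 and 0.65, and Xpo5, the exporter of microRNA precursors, at 0.48. The score of that list differed by 0.18, by 0.11 without WT 2, by 0.10 without KO 1 and by 0.68 (SE 0.13) with position in the model. Cell cycle genes were higher in 19 of 28 members (median 0.25, camera adjusted p = 0.000357, adjusted p = 0.557 with an estimated correlation), and Mcm6 (1.04) and Cenpa (0.73) passed over the list alone. The cell cycle score differed by 0.28, by 0.17 without WT 3 and by 0.71 (SE 0.30) with position in the model. The values with position rest on a single WT array, WT 2, and a single KO array, KO 1, each set against HET arrays. On the let-7, other microRNA target and biogenesis scores WT 2 was the lowest and KO 1 the highest of all arrays. The larger differences with position are therefore no firmer than the others.

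Of the 9 lists called here, 9 kept their sign with slide as a block and 6 had the same sign on each of the 3 slides. With an estimated correlation, and with fry, 0 of the 9 were called. Position in the model left 6 of the 9 called, and with normexp on all spots 9 lists were called, 8 of them among the 9 here. With normexp estimated on all spots, as planned, 4 genes passed, Spink5 and Emid1 as higher and Basp1 and Ltf as lower, and without KO 1, KO 2, WT 1 or WT 2 there were 6, 2, 1 and 1. With position in the model 3 of 21276 genes passed, S100g, Fxyd4 and Lcn2, all lower in KO. The split of genes at an unadjusted p under 0.05 depended on the normalization, with 38.5% higher here, 51.4% with the scanner's own log ratio, 56.6% in the sample channel alone and 62.8% with median centring.

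**Figure D2:**
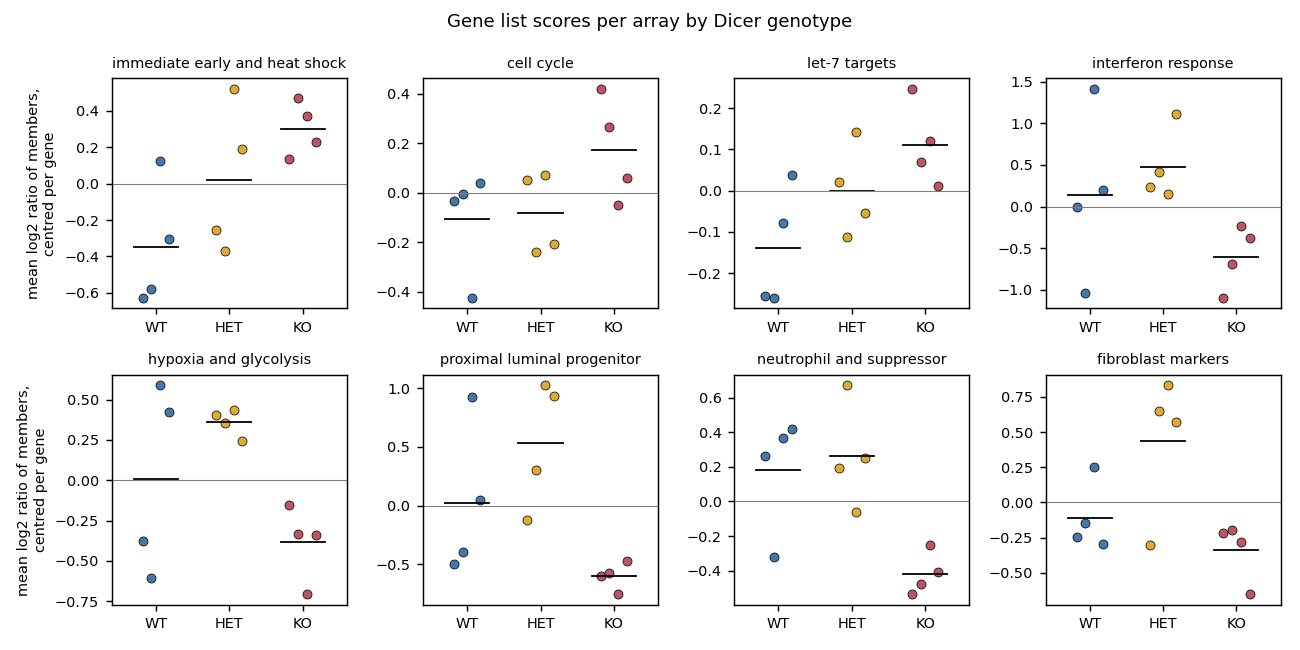
Score of 8 gene lists on each array (mean over members of the log2 ratio less the gene's mean), by genotype, with a line at the genotype mean. The immediate early score averaged 0.30 in KO and −0.35 in WT, and the interferon score averaged −0.60 in KO, 0.14 in WT and 0.48 in HET.

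The comparison of HET with WT asks what the loss of a single copy of Dicer1 changes. Markers of stromal cells stood higher in HET than in WT, with 14 of 14 fibroblast markers and 14 of 14 smooth muscle markers on the higher side (adjusted p = 0.490 and adjusted p = 0.511 with an estimated correlation). HET 1 had the lowest HET scores, −0.30 and −0.33. It stood apart for fibroblast markers only, since HET 2 was also low for smooth muscle markers, at 0.02. Genes of epithelial-mesenchymal transition (EMT) and invasion, of proximal luminal progenitors and of hypoxia also stood higher as groups (adjusted p = 0.490, 0.511 and 0.511 with an estimated correlation). The EMT list also holds the epithelial adhesion genes Cdh1 and Epcam, so a shift of the whole list does not measure EMT. No single gene passed, and no list member passed over its list alone.

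Limma called 0 of 24991 genes, with 842 at an unadjusted p under 0.05 (414 higher, 428 lower), where chance gives 1250, and 0 genes with normexp on all spots. With position in the model 4 of 21596 genes passed, S100g, Cxcl17, Cyp2f2 and Raet1e. The lowest adjusted p was 0.999, so each gene named below has that adjusted p in this comparison. Among genes of lowest p, Cdk19 was higher by 2.39 with 2 HET and 1 WT values, Xlr4b by 1.44, Stk38 by 0.76 and Nptn by 0.75. Abca9, Ces1b, Rfesd and Elac1 were lower by −1.07, −0.79, −0.67 and −0.55, and 2 other Abca9 probes gave −0.23 and 0.10. Ces1b and Rfesd were above background on 2 of 4 HET arrays and Abca9 and Elac1 on 3 of 4. Xlr4b was above it on 3 of 4 WT arrays, with overlap between the groups.

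The fibroblast list had a median of 0.66 (camera adjusted p = 1.28e-06, adjusted p = 0.490 with an estimated correlation), and the smooth muscle list a median of 0.39 (camera adjusted p = 0.006, adjusted p = 0.511 with an estimated correlation). The EMT list was higher in 18 of 21 members (median 0.38, camera adjusted p = 1.63e-05, adjusted p = 0.490 with an estimated correlation). Its member of lowest p was Tnc, the gene of the matrix protein tenascin C, at 0.69, above background on 3 of 4 HET arrays. Proximal luminal genes were higher in 14 of 16 members (median 0.43, camera adjusted p = 0.00147, adjusted p = 0.511 with an estimated correlation), and basal epithelial genes in 13 of 17 (median 0.35, camera adjusted p = 0.00795, adjusted p = 0.511 with an estimated correlation). Hypoxia genes were higher in 13 of 15 members (median 0.37, camera adjusted p = 0.00228, adjusted p = 0.511 with an estimated correlation). Inflammatory genes were higher in 18 of 22 members (median 0.21, camera adjusted p = 0.00423, adjusted p = 0.511 with an estimated correlation). Interferon genes were higher in 18 of 22 (median 0.28, camera adjusted p = 0.011, adjusted p = 0.639 with an estimated correlation). Immediate early genes were higher in 11 of 15 (median 0.19, camera adjusted p = 0.01, adjusted p = 0.511 with an estimated correlation).

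All 9 lists kept their sign with slide as a block, but 5 of the 9 lost their call there, and 2 of 9 had the same sign on each of the 3 slides. Position in the model left 5 of the 9 called, and with normexp on all spots 11 lists were called, 7 of them among the 9. The fibroblast score differed by 0.55, by 0.52 with slide as a block, and by −0.00416, 0.85 and 0.45 within slides 1, 2 and 3. The interferon score differed by 0.34, by 0.15 with slide as a block, and by 0.04, 0.93 and −0.78 within them. Single arrays moved it, to −0.0558 without WT 2, 0.76 without WT 3 and 0.12 without HET 4. The smooth muscle score differed by 0.40, by 0.14 without WT 4, 0.22 without HET 3, 0.25 without HET 4 and 0.62 without HET 1, and by a list median of −0.19 with position in the model. WT 2 also moved the inflammatory score from 0.39 to 0.13, the hypoxia score from 0.35 to 0.15 and the basal score from 0.35 to 0.20 when left out. The hypoxia score was 0.23 without WT 1 and 0.55 without WT 3, the proximal luminal score of 0.51 was 0.34 without WT 1 and 0.81 without WT 3, and the immediate early score of 0.37 was 0.20 without HET 3. Without WT 1 the number of lists called was 4, and without WT 2 it was 5. At position 3, which HET shared with WT 2 alone, the scores differed by 1.23 for interferon, 1.03 for hypoxia and 1.09 for inflammatory genes. For smooth muscle markers the difference there was −0.16.

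The comparison of KO with HET asks what the loss of the second copy of Dicer1 changes, and here single genes passed. Emid1 rose 5.48-fold in KO against HET, and the chromatin gene Atrx rose 2.21-fold. Setd5, another chromatin gene, rose 2.27-fold at 1 probe, while its 2 other probes gave 0.09 and −0.03 on the log2 scale. Lratd1 fell 7.98-fold and Clic6, of the chloride intracellular channel family, fell 2.89-fold. Groups of interferon, proximal luminal, hypoxia, inflammatory and stromal genes stood lower in KO (adjusted p = 0.285 to 0.504 with an estimated correlation, so none was called there).

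Limma called 5 of 25100 genes, 3 higher and 2 lower, each by at least 1 on the log2 scale. The count depended on the setting, from 0 at an offset of 16 to 151 with array weights. At an unadjusted p under 0.05 there were 2770, 866 higher and 1904 lower, where chance gives 1255. Emid1 averaged 2.83 ± 0.81 in KO and 0.38 ± 0.24 in HET (SD, n = 4 each), a change of 2.45 (SE 0.33, adjusted p = 0.0404). Setd5 averaged 1.07 ± 0.16 and −0.12 ± 0.09, a change of 1.19 (SE 0.15, adjusted p = 0.0332). Atrx averaged 0.78 ± 0.26 and −0.36 ± 0.13, a change of 1.14 (SE 0.15, adjusted p = 0.0404). Lratd1 averaged 1.24 ± 0.80 and 4.24 ± 0.49, a change of −3.00 (SE 0.36, adjusted p = 0.0332), with −2.33 at its other probe. Clic6 averaged 0.52 ± 0.21 and 2.05 ± 0.34, a change of −1.53 (SE 0.21, adjusted p = 0.0404), with −1.62 at its other probe. With slide as a block the changes were 2.30 for Emid1, 1.20 for Setd5, 1.13 for Atrx, −2.88 for Lratd1 and −1.50 for Clic6. Within slides 1, 2 and 3 they were 3.16, 1.89 and 1.78 for Emid1, 1.34, 1.28 and 0.91 for Setd5, and 0.95, 1.19 and 1.27 for Atrx. For Lratd1 they were −2.81, −1.82 and −3.62, and for Clic6 −1.50, −1.60 and −1.38.

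**Figure D3:**
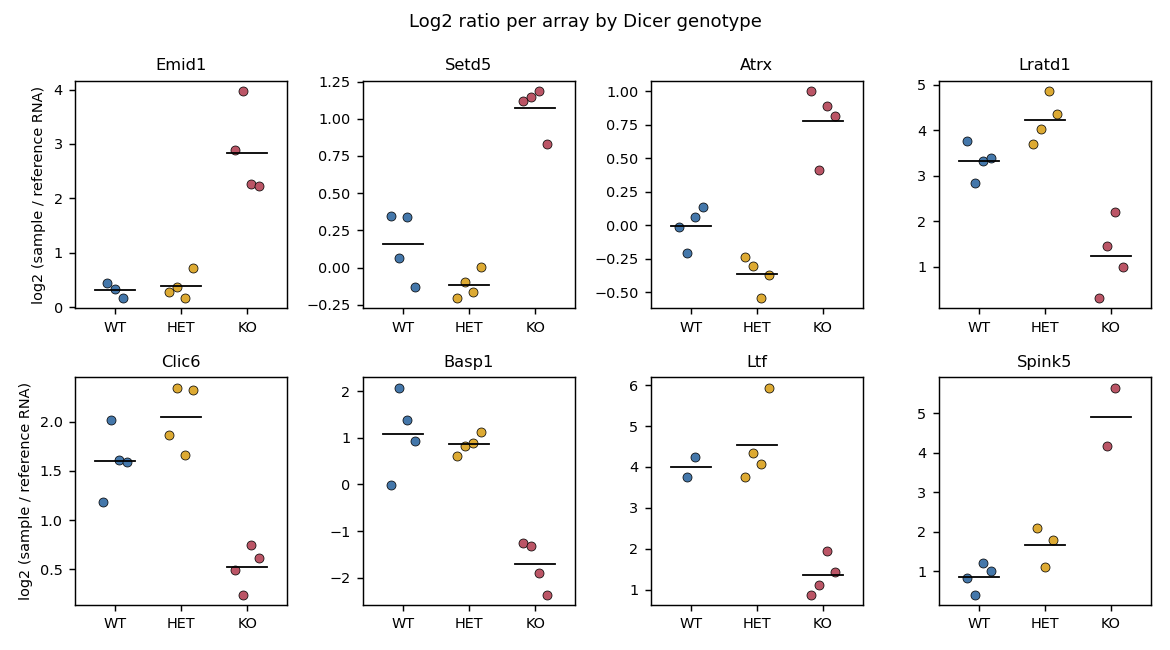
Log2 ratio of sample to reference on each array for 8 genes, by genotype, with a line at the genotype mean. Emid1 averaged 2.83 in KO and 0.38 in HET, and Lratd1 averaged 1.24 in KO and 4.24 in HET, with no overlap between these 2 genotypes.

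Close to the threshold, Basp1 was lower by −2.57 (SE 0.37, adjusted p = 0.0517), Ltf by −3.18 (SE 0.43, adjusted p = 0.0517) and Spink5 higher by 3.24 (SE 0.44, adjusted p = 0.0744, values on 2 KO and 3 HET arrays). The second Ltf probe gave −3.98 (SE 0.31, adjusted p = 0.000287 in the fit of all probes). In that fit of all probes Basp1 and the first Ltf probe passed as well (limma adjusted p = 0.0436 each), as did the other Lratd1 probe (limma adjusted p = 0.0321). Spink5 did not pass there.

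Interferon response genes were lower in 22 of 22 members, with a median of −1.18 (camera adjusted p = 2.88e-09, adjusted p = 0.366 with an estimated correlation). Adjusted over the list alone, 6 passed and 0 over all genes. They included Irf7, a regulator of interferon genes, at −2.66 (SE 0.77), Ifit3 at −2.29 (SE 0.66) and Isg15 at −1.35. The score differed by −1.08, by −0.91 with slide as a block, and by −1.13, −0.65 and −1.02 within slides 1, 2 and 3. Inflammatory genes were lower in 20 of 22 members (median −0.54, camera adjusted p = 2.22e-05, adjusted p = 0.285 with an estimated correlation), and 2 passed over the list alone, Cxcl17 at −3.29 (SE 0.88) and Lcn2 at −2.71 (SE 0.58). Neutrophil markers were lower in 10 of 13 members (median −0.29, camera adjusted p = 0.000987, adjusted p = 0.285 with an estimated correlation), with Ltf and Arg1 (−2.49, above background on 2 of 4 KO arrays) passing over the list alone.

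Proximal luminal progenitor genes were lower in 14 of 16 members (median −1.18, camera adjusted p = 8.75e-08, adjusted p = 0.285 with an estimated correlation). Over the list alone 5 passed, among them Ly6d at −3.16 (SE 0.72), Ly6a at −1.87 and Krt4 at −1.28. The score differed by −1.13, by −0.97 with slide as a block, and by −0.47, −1.06 and −1.45 within the slides. Basal epithelial genes were lower in 14 of 17 members (median −0.52, camera adjusted p = 0.0169, adjusted p = 0.413 with an estimated correlation), with 0 passing over the list alone. Hypoxia and glycolysis genes were lower in 13 of 16 members (median −0.83, camera adjusted p = 1.46e-06, adjusted p = 0.285 with an estimated correlation). Over that list alone 8 passed, among them Pdk1 at −1.75 (SE 0.41), Slc2a1 at −1.21 (SE 0.30) and Pgk1 at −1.19. Ldha, also among the 8, had 2 KO and 2 HET values.

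Fibroblast markers were lower in 13 of 14 members (median −0.65, camera adjusted p = 1.05e-05, adjusted p = 0.285 with an estimated correlation). Over the list alone 7 passed, such as Pdgfrb at −1.37 (SE 0.35). Of the 7, Lum (−2.10, SE 0.62), Col1a1, Col1a2 and Col6a1 overlapped between the groups, and Dcn had 1 KO and 2 HET values. Smooth muscle markers were lower in 12 of 14 (median −0.57, camera adjusted p = 0.0119, adjusted p = 0.504 with an estimated correlation), although the median turned to 0.15 with position in the model and the score differed by 0.48 on slide 1. The fibroblast score differed by 0.09, −0.93 and −1.35 within slides 1, 2 and 3 and by −0.69 with slide as a block. The EMT list was lower in 16 of 21 members (median −0.54, camera adjusted p = 0.000161, adjusted p = 0.285 with an estimated correlation), and its median turned to 0.07 with position in the model. Of the 5 members that passed over the list alone, all lower, Cdh1 (−0.89) and Epcam (−1.08) are epithelial adhesion genes, while Tnc (−0.71, with overlap and above background on 2 KO and 3 HET arrays) and Mmp3 (−1.21) act on the matrix. The remaining member, S100a4, had 1 KO and 2 HET values.

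Cell cycle genes were higher in 23 of 27 members (median 0.26, camera adjusted p = 0.000161, adjusted p = 0.366 with an estimated correlation), with 0 passing over the list alone. Immediate early and heat shock genes were called as higher (median 0.56, camera adjusted p = 0.000559, adjusted p = 0.285 with an estimated correlation), with 9 members higher and 6 lower. Their score differed by 0.28, by 0.15 without HET 2 and by 0.45 without HET 3. Over the list alone Fos (1.37), Egr1 (1.22), Fosb (1.09), Dusp1 (0.99) and Zfp36 (0.78) passed as higher and the small heat shock gene Hspb1 (−2.03) as lower, with overlap between the groups for Fosb, Dusp1 and Hspb1. The let-7 target list was not called (median 0.19, camera adjusted p = 0.0615). Xpo5 was higher by 0.62 and Mybl2 by 0.72, each passing over its own list alone.

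Of the 11 lists called, 11 kept their sign with slide as a block and 7 had the same sign on each slide, while 0 were called with an estimated correlation or with fry. Position in the model left 6 of the 11 called, and with normexp on all spots 9 lists were called, 8 of them among the 11. With normexp on all spots 4 genes passed, 2 of them among the 5, and Atrx, Lratd1 and Clic6 had adjusted p of 0.071, 0.35 and 0.413, while 2 genes passed without KO 2, 1 without KO 3 and 0 without each other KO or HET array. With position in the model 0 genes passed, and KO differed from HET by 2.35 for Emid1, 1.17 for Setd5, 1.34 for Atrx, −3.89 for Lratd1 and −1.84 for Clic6. List scores can be compared at position 2, where KO 1 stood against HET 2 and HET 4. They differed by −1.86 for interferon, 0.64 for cell cycle, −0.16 for basal, −0.45 for hypoxia and 0.03 for smooth muscle genes. Of the genes at an unadjusted p under 0.05, 31.3% were higher here, 48.9% with the scanner's log ratio, 53.6% in the sample channel alone and 62.0% with median centring.

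Across the 3 genotypes together, limma's F test called 4 of 24961 genes, Basp1, Lratd1, Setd5 and Spink5, each with an adjusted p of 0.0442. An F test that takes each gene's missing values into account exactly called Emid1 as well. Basp1 averaged 1.09 in WT, 0.86 in HET and −1.71 in KO. Spink5 averaged 0.86, 1.67 and 4.90. With normexp on all spots the F test called 5 genes, and without WT 2 it called 11, without WT 1 or KO 3 it called 1, and without each other array 0. It called 1 gene with slide as a block, 0 with replicate number as a block and 8 other genes with position in the model.

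The test of HET against the midpoint of WT and KO asks whether loss of a single copy gives a level other than the exact midpoint. A list that departs from the midpoint can still lie between WT and KO. Camera called 10 lists, and 0 were called with an estimated correlation or with fry. Against the midpoint of the other genotypes, fibroblast markers were higher in HET by a median of 0.78 (camera adjusted p = 4.26e-08, adjusted p = 0.308 with an estimated correlation). Proximal luminal genes were higher in 16 of 16 members by a median of 0.67 (camera adjusted p = 5.42e-08, adjusted p = 0.308 with an estimated correlation), and interferon genes by 0.80 (camera adjusted p = 5.42e-08, adjusted p = 0.491 with an estimated correlation). Hypoxia genes (0.62, 2.39e-07), EMT genes (0.43, 6.21e-07) and inflammatory genes (0.43, 6.98e-06) were also called as higher, each with adjusted p = 0.308 with an estimated correlation. Smooth muscle (0.40, camera adjusted p = 0.00147), basal (0.36, 0.00245) and housekeeping genes (0.20, 0.0236) followed as higher, and cell cycle genes were lower (−0.14, 0.0304). With an estimated correlation their adjusted p were 0.511, 0.491, 0.567 and 0.567. Directions turned for smooth muscle genes with position in the model (−0.11), for housekeeping genes with median centring (−0.0354) and for cell cycle genes with normexp on all spots (0.06) and in the sample channel alone (0.0020). Limma called 0 of 24961 genes against the midpoint, with 1592 at an unadjusted p under 0.05 (1069 higher, 523 lower), where chance gives 1248. The lowest adjusted p was 0.618. With normexp on all spots 0 genes and 8 lists were called.

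The changes of KO and of HET from WT share the WT arrays. Across 24961 genes, which are not independent replicates, their log2 differences correlated with r = 0.277. Unchanged groups made by reshuffling the arrays' deviations gave a mean r of 0.515, with 95% of draws between 0.127 and 0.894. With the WT arrays split into 2 and 2, r averaged −0.207. The covariance was 0.0270, against a mean of 0.0510 in those draws (95% between 0.00905 and 0.102) and 0.0407 in a simulation of independent genes. Of the genes 61.8% had the same sign, against a mean of 68.1% in those draws.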

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

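The tests of explanations for the 3 patterns below were chosen after the patterns had been seen, and the check for single samples far from the others was planned.

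A sample far from the other samples of its genotype was found in 15 of 399 groups of 4 values examined, where chance gives about 1 in 20, or 19.95. The figures here are the gap to the nearest sample as a share of the whole range. In WT, Galnt10 had WT 2 at 1.87 against 0.91 to 1.00 (0.908). Plp1 had WT 1 at 0.38 against 0.02 to 0.05 (0.918), and Pdk1 had WT 3 at 0.72 against −1.14 to −0.87 (0.855). The cell cycle score had WT 3 at −0.43 against −0.03 to 0.04 (0.839). In HET, Irf9 had HET 4 at 1.97 against 1.56 to 1.59 (0.932), and Isg15 had HET 4 at 2.70 against 1.33 to 1.38 (0.966). Col3a1 had HET 1 at −2.44 against −0.77 to −0.43 (0.832). Upk3a had HET 2 at 0.64 against −0.24 to −0.10 (0.834), and Cdh5 had HET 2 at 0.70 against 0.40 to 0.45 (0.847). The imprinted gene score had HET 3 at 0.30 against −0.07 to −0.04 (0.935), and the nerve and Schwann cell score had HET 1 at −0.23 against 0.29 to 0.38 (0.846). In KO, Cldn5 had KO 1 at −0.18 against 0.30 to 0.35 (0.902), and Tnni2 had KO 1 at −0.36 against 0.18 to 0.24 (0.900). Plp1 had KO 2 at −0.24 against 0.17 to 0.23 (0.867), and Mbp had KO 4 at −1.53 against 0.74 to 1.07 (0.872).

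Seminal vesicle secretory genes, 6 of which were measured and none of which another list holds, varied within each genotype, with list scores spanning 6.74 in WT, 5.68 in HET and 6.95 in KO. A secretory state in which the luminal secretory genes of the prostate rise as well was argued against by the sign of their change. The luminal secretory score changed by −0.0761 (SE 0.0355) per unit of the seminal vesicle score. The bound of 0.5, set for both moving together, decides little, since the luminal score varied far less and a shared state could give a smaller slope. Seminal vesicle RNA of a constant makeup was also argued against, since Sva minus Svs2 ranged over 7.61 among the 6 arrays with high Svs2. Seminal vesicle tissue of varying makeup in some samples stays open, since the first component held 88.9% of the list's variance (51.5% in shuffled draws), and the neuroendocrine and epididymal scores followed it within genotypes (r = 0.933 and 0.726, n = 12), which shared regulation would also give. The design names no biological difference within a genotype, and no other biological explanation was tested.

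Interferon response genes were lower in KO than in WT, by a score of −0.743 (SE 0.474), and by −0.320 without WT 3. Pooled T and B cell markers were not lower in KO, with a difference of 0.0559 (SE 0.0942), against −0.372 needed for 50% of the interferon difference. The T cell score ran only from −0.0967 (HET 1) to 0.108 (KO 3) over all arrays, so T cell markers could hardly have shown such a fall. The test therefore does not decide whether KO samples held fewer T and B cells. Fewer macrophages and neutrophils stay open, since their pooled markers differed by −0.390 (SE 0.201). The difference of −0.743 was itself under 2 standard errors from 0, so it is not told apart from spread between samples. The tests that follow therefore decide little. Slides and array position stay open, with −0.760 (SE 0.456) with slide in the model and −0.634 (SE 0.878) with position. For the 2 KO arrays of the protocol's amount the difference was −1.04 (SE 0.588), larger than with all 4. KO 3 and KO 4, of smaller amount, scored −0.235 and −0.382, against −1.10 and −0.692 for KO 1 and KO 2. The lower score was thus not confined to the arrays of smaller amount, but the spread leaves their part undecided. An effect of Dicer1 loss on interferon signalling may also account for the difference and was not separated from these.

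Immediate early genes were higher in KO than in WT, by a score of 0.649 (SE 0.228). Slide differences were argued against as the whole source, since the difference with slide in the model was 0.609 (SE 0.181), with the same sign on each slide. So were the smaller RNA amounts, since the 2 KO arrays of the protocol's amount differed from WT by 0.652 (SE 0.296). Array position stays open, since with position in the model the difference was 0.939 (SE 0.622), larger but under 2 standard errors from 0. The handling time of the tissue before RNA extraction, which these genes follow, is not in the labels and may also have differed.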

How the results depend on the processing

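Fits with outlier spots kept, with the seminal vesicle score as a covariate, with array position in the model and with an exact F test were chosen after results were seen. Normexp on all spots was the planned main setting, and the background setting used here replaced it after counts had been seen. The other alternatives were planned. Of the lists called, 1010 values kept their direction and side of the threshold, 14 reversed and the others lost the call. For the named genes that were called 74 values kept both, 71 lost the call and 0 reversed. Aquantile normalization leaves log ratios as they are, so it tests nothing here. Signal over background limits what could be seen on HET 3, with 58.0% of spots well above it, and on KO 4, with 52.5% in the reference. Seed sites of microRNAs were not tested, since no 3′ untranslated regions were available. Except where stated, the cause of a difference was not tested.

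The number of genes called for KO against WT was 0 and rose to 3 without background correction, 9 with the scanner's log ratio, 1 with the authors' table, 2 with scaling between arrays, 2 in the sample channel alone, 2 for probes well above background on all 12 arrays, 3 with all probes, 4 without the 2 arrays of smaller RNA amount, 3 with outlier spots kept, 4 with normexp on all spots and 3 with position in the model. It ran from 0 to 6 when single arrays were left out, with 6 without KO 1, 2 without KO 2 and 1 without WT 1 or WT 2. The 9 lists became 0 with an estimated correlation, 0 with fry, and 4 to 10 without single arrays, with 4 without WT 3. For HET against WT the gene count of 0 became 4 with position in the model and stayed 0 in every other alternative run, and the 9 lists became 5 with median centring, 5 with slide as a block, 0 with an estimated correlation, 0 with fry, and 4 to 13 without single arrays.

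The 5 genes of KO against HET became 0 at an offset of 16, 2 with median centring, 3 without a brightness filter, 22 with slide as a block (5 shared), 0 with position in the model, 113 in a fit of these 2 genotypes alone (5 shared), 151 with array weights (5 shared), 9 without the 2 arrays of smaller RNA amount (2 shared) and 9 with outlier spots kept (5 shared). Without single arrays the count was 0 to 2, with 2 without KO 2, 1 without KO 3 and 0 without each other HET or KO array. The 11 lists became 0 with an estimated correlation and 0 with fry. Against the midpoint, the gene count of 0 became 1 with the scanner's log ratio, 1 with slide as a block and 4 with position in the model, and the 10 lists became 0 with an estimated correlation and 0 with fry. The F test's 4 genes became 7 with the scanner's log ratio, 7 with outlier spots kept, 8 with position in the model (0 shared), 1 with slide as a block, and 0 at an offset of 16, with median centring, in the sample channel alone, without a brightness filter, with array weights and with the seminal vesicle score as a covariate. Without single arrays that count ran from 0 to 11, with 11 without WT 2, 1 without WT 1 or KO 3 and 0 without each other array.

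With the replicate number as a block, KO against HET had 3 genes (1 shared) and the F test 0. The numbers do not pair the samples, since correlations of deviations between samples of the same number ran from −0.424 to 0.292, with 3 of 12 over 0.1 and 1 of 12 samples correlating best with its own number.

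The correlation of the KO and HET changes, 0.277, became 0.203 with slide as a block and reversed to −0.207 with the WT arrays split, where the shared arrays no longer add to it. The median of the other microRNA targets in KO against WT, 0.000313, turned to −0.0169 without background correction, −0.0168 for probes well above background on all 12 arrays, −0.0135 with the replicate block, −0.0161 with outlier spots kept and −0.0160 with normexp on all spots. The interferon median of HET against WT turned to −0.0251 without WT 2 and ran up to 0.817 without WT 3. Against the midpoint, the cell cycle median turned to 0.0020 in the sample channel and 0.0594 with normexp on all spots, and the housekeeping median to −0.0354 with median centring. Position in the model turned the hypoxia median of KO against WT to 0.540, the EMT median of KO against HET to 0.0722, and the smooth muscle median to −0.186 for HET against WT, 0.150 for KO against HET and −0.111 against the midpoint.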

Other observations

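The counts over other splits of the samples were planned, and the tests of genes and lists between slides were chosen after results were seen.

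Of the immune and vascular marker lists, only that of neutrophils was called for KO against WT, and with an estimated correlation it was not (adjusted p = 0.375 with an estimated correlation). Macrophage markers were lower in KO than in WT by a median of −0.16 (camera adjusted p = 0.268), endothelial markers by −0.22 (adjusted p = 0.469) and T cell markers by −0.05 (adjusted p = 0.848), while B and plasma cell markers were higher by 0.17 (adjusted p = 0.119). The endothelial score was lower in KO by −0.214 (SE 0.0795), by −0.171 (SE 0.0609) with slide as a block and on each of the 3 slides (exact permutation p = 0.0571). Against HET, the complement gene C1qc was lower in KO by −1.33, with overlap between the groups, and passed over the macrophage list alone. Adipocyte, blood, urothelial, fibroblast, smooth muscle and neuroendocrine markers had an adjusted p of 0.752 for KO against WT, as had imprinted genes, p53 targets, CDK inhibitors, EMT genes and housekeeping genes. Basal epithelial, nerve and Schwann cell and epididymal markers had 0.807, skeletal muscle markers 0.264, FOXO and PI3K feedback genes 0.848 and inflammatory genes 0.083.

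Within lists that were not called, a few members passed over their list alone for KO against HET, and 0 over all genes. Igfbp5, a binding protein of insulin-like growth factors, was lower in KO by −2.05 (SE 0.40), and the CDK inhibitor gene Cdkn2b by −0.74. Of the p53 targets, the apoptosis gene Pmaip1 was lower by −1.67 and Aen by −0.68, although another Aen probe gave 0.07.

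Other splits of the samples into groups of the same sizes tell how often chance gives as large a count. For KO against HET, 1 of 35 splits, the real one, gave 5 genes or more, and the highest other count was 0. This is the smallest share that 35 splits allow, and several counts were checked in this way. The 5 genes also rest on a background setting chosen after counts were seen. The count argues against chance there but does not exclude it. Chance is also not excluded for the 11 lists of that comparison (2 of 35 splits, highest other 11). Nor is it for the 9 lists of KO against WT (6 of 35, highest other 11), the 9 of HET against WT (9 of 35, highest other 12) and the 10 against the midpoint (11 of 100, highest other 12). Where the real gene count was 0, every split reaches it, so the splits decide nothing. These were KO against WT (35 of 35, highest other 11), HET against WT (35 of 35, highest other 245) and the midpoint (100 of 100, highest other 58). The split of WT 1, WT 4, HET 1 and HET 2 from WT 2, WT 3, HET 3 and HET 4 called those 245 genes. It is the most extreme of the other splits, and what sets its groups apart was not tested. The second group holds the 3 WT and HET arrays of slide 3, but an F test with the slides as groups called 0 genes. For the F test 6 of 100 splits gave 4 genes or more (highest other 265), and chance is not excluded.

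Slides were compared in the same way. With genotype in the model, 1 of 24830 genes differed between slides and 4078 had an unadjusted p under 0.05, while with slide in the model genotype called 1 gene and 2937 had an unadjusted p under 0.05. Lists were also called between slides, but with an estimated correlation 0 of the 10 calls below were kept (adjusted p = 0.417 for slide 2 and 0.675 for slide 3), and 0 with fry. Housekeeping genes were lower on slide 2 than on slide 1 by a median of −0.53 (camera adjusted p = 4.74e-06), as were hypoxia genes by −0.52 (adjusted p = 0.00227) and FOXO and PI3K feedback genes by −0.41 (adjusted p = 0.00495). On slide 3, against slide 1, interferon genes were higher by 0.63 (adjusted p = 4.32e-05), proximal luminal genes by 0.71 (adjusted p = 0.000137), macrophage markers by 0.41 (adjusted p = 0.00365), and fibroblast and smooth muscle markers by 0.37 and 0.45 (adjusted p = 0.0488 each). Cell cycle genes were lower there by −0.24 (adjusted p = 0.00344) and FOXO and PI3K feedback genes by −0.25 (adjusted p = 0.00751). Slide 3 held 2 HET arrays against 1 WT and 1 KO array, and with slide as a block the interferon score of HET against WT went from 0.34 to 0.15 and the fibroblast score from 0.55 to 0.52. WT 4 and HET 1, adjacent on slide 1, had the highest correlation of any pair across probes, 0.904, and their values differed with an SD of 0.309.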
